A study of Mus musculus and Homo sapiens with 12 samples.

How the data were processed

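RNA-seq libraries depleted of ribosomal RNA were compared in 2 triple-negative breast cancer cell lines: 4T1, a mouse mammary carcinoma line, and MDA-MB-231, a human line. Each line had 3 libraries labelled Pri and 3 labelled LM, which makes 12 libraries in 4 groups. The design text of the series names derivatives called 4T1-LM3 and MDA-MB-231/LM3 and the parental cells of each, so LM was read as the derivative and Pri as the parental cells. Nothing in the labels says whether the 3 libraries of a group come from separate cultures, so the p-values measure only the spread between samples. Replicate numbers were not used to pair Pri with LM libraries.

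Per the labels, the authors used FastQC, HISAT2, HTSeq 0.13.5, DESeq2 and limma 3.40.6, with genome builds GRCm38 for mouse and GRCh38 for human. The deposited files give raw read counts and FPKM for each gene of each library. Per the file headers, 1 column holds counts and the other FPKM. The FPKM equal the count divided by a gene length and by the total of the listed counts: the length implied by each library deviated from the mean over libraries by at most 0.0488% in 4T1 and 0.0408% in MDA-MB-231. The 4T1 files list 27116 genes and the MDA-MB-231 files 31491. Of the mouse gene identifiers, 27109 were found in GENCODE M21, from which mouse positions on GRCm38 were taken. No human annotation was used, so human genes carry no positions.

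The plan made before the data were examined took limma on log2 FPKM as the main test, with edgeR if the files held raw counts instead. They held both, a case the plan did not name. The counts were then taken as the main data, with edgeR 4.0.16 in R 4.3.3, and limma became an alternative. Genes were kept by filterByExpr with a minimum count of 10 and libraries were scaled by TMM. LM was tested against Pri in each line with the two-sided quasi-likelihood test and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 were called. Library totals ranged from 18351785 to 33025859 counts. A gene with no count in a library is compatible with up to 3 counts, which is the floor used for folds, and genes with 1 to 3 counts in a group carry an exact 95% interval of the count ratio. Intervals and floors cover counting error only. FPKM are given as the mean and SD of 3 libraries, and log2 changes as LM minus Pri with their SE. The SE is the absolute log2 change divided by the square root of the quasi-likelihood F statistic. For genes with 1 to 3 counts in a group it is too narrow, and the interval of the count ratio is the better guide.

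Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with the preset correlation of 0.01 and again with an estimated correlation. The 41 lists were fixed before the data were examined. Of these, 37 had at least 3 tested members in 4T1 and 39 in MDA-MB-231. For the study's own genes an exact two-sided permutation test of 3 against 3 libraries was run as well, whose smallest possible p is 0.1. The lines were compared through 12786 genes whose human symbol equals the upper-case mouse symbol. Calls shared by both lines were compared with independent lists by Fisher's exact test, and the difference between the lines was the interaction term of an edgeR fit to all 12 libraries, which share 1 estimate of spread.

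Genes are named by a rule fixed before the data were examined. It takes RGCC, PLK1, PRKAA1 and PRKAA2. In each line it takes the 8 called genes with the largest rise and the 8 with the largest fall in log2(FPKM + 0.5), among genes whose LM libraries all lie on one side of the Pri libraries and whose higher group has a mean FPKM of at least 5. Clone names, predicted genes, pseudogenes, small RNAs and histones are excluded. Human pseudogenes were recognised by a symbol ending in a digit and P. The rule also takes up to 4 members of each list described: the called ones with the largest change or, with fewer than 2 called, the most abundant. It takes genes called in both lines, and the 6 genes with the lowest adjusted p for the difference between the lines. Genes outside the rule are named as chosen after their values were seen. Some genes that the rule takes are not reported here.

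The alternatives were: no filter on low counts, a filter on FPKM of at least 2 in 3 libraries, median-of-ratios scaling, library totals without the 20 most abundant genes, no abundance trend, replicate number as a block, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 0.5, 0.1 and 1, limma on TPM, quantile normalization, an absolute log2 change of at least 1, and leaving out each library in turn. Library totals without TMM were added after the data had been seen. The limma settings, TPM and quantile normalization among them, kept genes with an FPKM of at least 0.5 in 3 libraries. Tool and filter thus changed together there. The procedure was tested on simulated data with planted changes before use. At a planted fold of 2, edgeR called 14.0% of the changed genes at the spread of 4T1 and 76.0% at that of MDA-MB-231; at a fold of 4 it called 84.0% and 96.0%. Of the genes left unchanged it called 11 and 10. The 4T1 simulation called 42 of 50 genes at a fold of 4 and 49 of 50 at 8, against 4 genes in the real data. More calls ease the Benjamini-Hochberg cut-off, so these shares may overstate what the real test could find. Figures were drawn with matplotlib 3.10.9.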

Results

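The data were gene-level read counts and FPKM from cultured 4T1 mouse and MDA-MB-231 human breast cancer cells, each as Pri and LM cells with n = 3 libraries per group. Library totals were 21073734 to 28457964 counts in 4T1 Pri and 26726674 to 33025859 in 4T1 LM. They were 18351785 to 20798513 in MDA-MB-231 Pri and 19693214 to 24814971 in MDA-MB-231 LM. In 4T1 the predicted gene Gm26917 took 19.9% to 22.4% of the counts of a library and Gm42418 took 2.51% to 3.26%. The most counted gene in MDA-MB-231, EEF1A1, took 0.849% to 1.01%. Within groups, libraries of 4T1 differed from one another by 23.8 to 83.4 times the variance that counting alone gives, and those of MDA-MB-231 by 2.82 to 16.6 times. The biological coefficient of variation was 25.5% in 4T1 and 9.41% in MDA-MB-231. Transcripts of the mitochondrial genome made up 0.576% ± 0.0886 (SD, n = 3) of the counts in 4T1 Pri and 0.428% ± 0.0540 in 4T1 LM. In MDA-MB-231 they made up 0.249% ± 0.0807 and 0.255% ± 0.0574.

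The title of the series names RGCC, the kinase PLK1 and the alpha 2 subunit of AMPK, encoded by PRKAA2, in lung metastasis. RGCC, a regulator of cell cycle, rose in MDA-MB-231 LM cells, from an FPKM of 2.26 ± 0.18 to 9.76 ± 1.32 (SD, n = 3), a log2 change of 2.10 ± 0.17 (SE) with an edgeR adjusted p of 9.67e-06. All LM libraries, with 187 to 288 counts, lay above all Pri libraries, with 44 to 49 counts. In 4T1 the log2 difference of Rgcc (chromosome 14, 79288756 to 79301645) was 2.12 ± 0.51, from an FPKM of 0.196 ± 0.0552 to 0.841 ± 0.358. It rested on 4 to 5 counts per Pri library and 11 to 29 per LM library and did not pass the threshold over all genes (adjusted p = 0.294; exact permutation p = 0.1, the smallest possible). The difference of RGCC between the lines was 0.02 ± 0.21 on the log2 scale (adjusted p = 0.985 for the interaction term). That fit shares 1 estimate of spread over both lines, and its SE is below the 0.51 of 4T1 alone. It therefore understates the error and does not show that the change is equal.

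PLK1 mRNA, which encodes a mitotic kinase, stood at an FPKM of 32.3 ± 2.11 in MDA-MB-231 Pri and 32.1 ± 2.58 in LM cells (SD, n = 3). Its log2 difference was -0.02 ± 0.08 (SE, edgeR adjusted p = 0.906). In 4T1, Plk1 (chromosome 7, 122159439 to 122169873) had an FPKM of 56.6 ± 14.5 in Pri and 74.0 ± 4.37 in LM cells, a log2 difference of 0.40 ± 0.21 that did not pass the threshold (adjusted p = 0.444; exact permutation p = 0.1). PRKAA2 had an FPKM of 5.32 ± 0.92 in MDA-MB-231 Pri and 5.71 ± 0.24 in LM cells, a log2 difference of 0.10 ± 0.10 (adjusted p = 0.609), which was -0.010 without Pri library 1. Prkaa2 was all but undetected in 4T1, with 0 counts in 5 libraries and 1 count in LM library 3, where 3 counts would give an FPKM of 0.0114 to 0.0179. The transcript of the other catalytic subunit, Prkaa1 (chromosome 15, 5143861 to 5181899), was present in 4T1 at an FPKM of 16.7 ± 0.90 in Pri and 15.2 ± 2.68 in LM cells. Its log2 difference was -0.11 ± 0.16 in 4T1, and that of PRKAA1 was -0.03 ± 0.10 in MDA-MB-231; neither passed the threshold. Signs turned for PLK1 without Pri library 1 (0.035) or LM library 2 (0.049), for PRKAA1 without Pri library 3 (0.020) or LM library 1 (0.064), and for Prkaa1 in 4T1 without LM library 3 (0.0036).

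**Figure D1:**
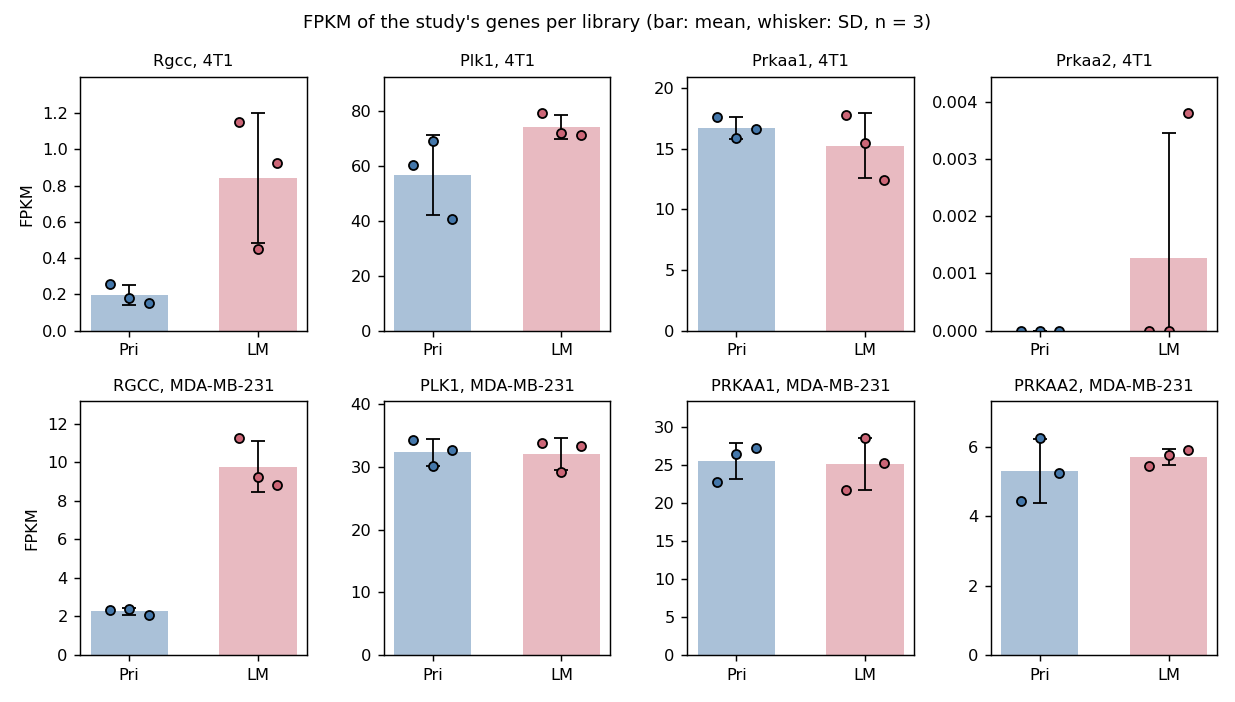
FPKM (vertical axes, each starting at 0) of RGCC, PLK1, PRKAA1 and PRKAA2 in the Pri and LM libraries of 4T1 (upper panels) and MDA-MB-231 (lower panels); points are libraries, bars the mean and whiskers the SD of n = 3. RGCC is higher in every LM library than in every Pri library of both lines, while Prkaa2 in 4T1 has 1 count in 1 library.

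The comparison of MDA-MB-231 LM with Pri cells asks which transcripts differ between the LM derivative and the parental line. Among the largest falls in LM cells were KISS1, the precursor of kisspeptins, and CCL2, a monocyte chemoattractant. KISS1 went from an FPKM of 20.9 ± 3.29 to 0.0616 ± 0.107 (SD, n = 3), a count ratio of 337 with a 95% interval of 115 to 1639, since LM cells had 3 counts. CCL2 fell from 13.0 ± 6.94 to 0.111 ± 0.0278 FPKM, a log2 change of -6.84 ± 0.47 (SE). ANKRD1, a target of the YAP coactivator, fell from 133 ± 15.7 to 16.7 ± 7.22 FPKM, a log2 change of -3.01 ± 0.24. The cytokine IL11 fell by 2.44 ± 0.30, the tricellular junction gene LSR by 4.16 ± 0.25 and the unconventional myosin gene MYO1D by 3.06 ± 0.17 on the log2 scale. IGFBPL1 (-2.79 ± 0.38) and RFPL4A (-5.84 ± 0.54) also fell. The 7 LM counts of RFPL4A all lie in LM library 3. Its value of -10.02 without that library is thus set against no LM counts and is no measured size. RFPL4A has close paralogs with which it may share reads.

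Higher in MDA-MB-231 LM cells were AKR1C4, of the aldo-keto reductases, and the organic anion transporter gene SLCO4A1. AKR1C4 had 3 counts in Pri cells and a count ratio of 300.1 with a 95% interval of 102 to 1458; the AKR1C genes are close paralogs, so reads may be misassigned among them. SLCO4A1 rose from an FPKM of 1.51 ± 0.32 to 7.65 ± 0.95 (SD, n = 3), a log2 change of 2.34 ± 0.15 (SE). The forkhead factor gene FOXQ1 rose by 2.08 ± 0.22, RASD1 by 1.63 ± 0.25, ATP9A by 1.69 ± 0.12, the intermediate filament gene NES by 1.51 ± 0.12 and LTBP1, whose product binds latent TGF-beta, by 1.51 ± 0.21. As the naming rule requires, every gene named in this and the preceding comparison of MDA-MB-231 had LM libraries all on one side of the Pri libraries. With edgeR, 2609 of 16792 tested genes were called, 1370 higher and 1239 lower in LM cells, of which 506 had an absolute log2 change of at least 1. Groups did not overlap for 33.4% of tested genes, where chance gives 10%. Without Pri library 3 the count was 1499, with 731 higher and 768 lower, and without LM library 3 the lower genes numbered 813. With replicate number as a block it was 4398, and under the limma settings 1678 to 1720.

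Genes of respiration and fuel use bear on the processes in the title of the series; respiratory subunits had few calls in MDA-MB-231. Of 37 complex I subunits, NDUFA3 (-0.69 ± 0.19) was called. Adjusted over the list alone edgeR called 0, while 6 had an unadjusted p under 0.05, DESeq2 called 1 and limma on log2(FPKM + 0.5) called 2, and the list's camera adjusted p was 0.658. Of 40 subunits of complexes II to V, ATP5F1C rose by 0.38 ± 0.07, and UQCRFS1 (-0.44 ± 0.07) and ATP5MF (-0.42 ± 0.13) fell. Adjusted over the list alone, 1 was higher and 1 lower (list adjusted p = 0.894). The median of that list was 0.02, its mean -0.02 and its camera direction down. Of 12 subunits encoded by mitochondrial DNA, 0 were called by edgeR, DESeq2 or limma and 0 had an unadjusted p under 0.05 (adjusted p = 0.872 for the list). Among them were MT-CO1 (0.20 ± 0.14), MT-CO3 (0.08 ± 0.20), MT-ATP6 (-0.02 ± 0.28) and MT-ND1 (-0.14 ± 0.27). Without the filter on low counts edgeR called 1 higher, MT-CO1 (adjusted p = 0.0246), and 4 lower; MT-CO1 was also called with replicate number as a block (0.0187). MT-CO3 turned to -0.15 and -0.12 without Pri library 1 or LM library 2. MT-ATP6 turned to 0.019, 0.33 and 0.20 without Pri library 2, Pri library 3 or LM library 1, and MT-ND1 to 0.16 and 0.090 without Pri library 3 or LM library 1. In fatty acid oxidation, 4 of 31 genes rose, namely EHHADH (0.88 ± 0.19), ACSL5 (0.68 ± 0.10), DECR1 (0.47 ± 0.08) and ACAA2 (0.39 ± 0.10), and 1 fell. The same numbers were called adjusted over the list alone, and the list had an adjusted p of 0.166. The call of ACAA2 was lost without Pri library 3 (adjusted p = 0.119). In the tricarboxylic acid cycle, FH (-0.34 ± 0.07), IDH3A (-0.29 ± 0.08) and SUCLG2 (-0.26 ± 0.07) of 22 genes fell, as many as adjusted over the list alone (list adjusted p = 0.693). Calls were lost for FH without Pri library 3 (adjusted p = 0.0509), for IDH3A with limma (0.0643) or without Pri library 1 (0.101), Pri library 3 (0.108), LM library 2 (0.0518) or LM library 3 (0.0744), and for SUCLG2 without Pri library 2 (0.111), Pri library 3 (0.148), LM library 2 (0.0512) or LM library 3 (0.161). They were also lost for NDUFA3 without Pri library 2 (0.0808), Pri library 3 (0.121), LM library 1 (0.0520) or LM library 3 (0.0785). ATP5MF lost its call without Pri library 2 (0.0752), Pri library 3 (0.221) or LM library 1, 2 or 3 (0.0586, 0.103 and 0.0829).

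Glycolysis genes in MDA-MB-231 included 8 higher and 1 lower of 23, and 10 higher and 1 lower adjusted over the list alone (list adjusted p = 0.103). PFKFB3 rose by 0.60 ± 0.09, ENO2 by 0.55 ± 0.12, ALDOC by 0.44 ± 0.10 and PFKP by 0.39 ± 0.09. Without Pri library 3 the adjusted p of ALDOC was 0.0759 and that of PFKP 0.0565. Among 10 AMPK subunits and upstream kinases, the scaffold gene CAB39 rose by 0.29 ± 0.08 and the gamma subunit gene PRKAG2 fell by 0.40 ± 0.11, both also when adjusted over the list alone (list adjusted p = 0.693). Neither was past the threshold with limma on log2(FPKM + 0.5), where the adjusted p were 0.0529 and 0.113. CAB39 also lost its call without Pri library 1 (0.0674), LM library 2 (0.0642) or LM library 3 (0.0659), and PRKAG2 without Pri library 3 (0.107). Of 35 genes of the G2/M phase, UBE2C (0.29 ± 0.08) and KIF20A (0.29 ± 0.08) rose and CENPF fell by 0.38 ± 0.09, the same numbers as adjusted over the list alone (list adjusted p = 0.707). Without Pri library 3 the adjusted p of UBE2C, KIF20A and CENPF were 0.0834, 0.0835 and 0.0938, and with limma that of CENPF was 0.0715. UBE2C was not called without Pri library 2 (0.116) or LM library 1 (0.0537) either, nor KIF20A without Pri library 2 (0.0936) or LM library 3 (0.0603).

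The YAP/TAZ target list fell in MDA-MB-231 LM cells: 12 of 22 genes were lower and 1 higher, with a median log2 change of -0.34 (camera adjusted p = 9.87e-05; adjusted p = 0.967 with an estimated correlation). Besides ANKRD1, the growth factor gene TGFB2 fell from 23.0 ± 1.35 to 7.82 ± 2.59 FPKM (SD, n = 3) and NUAK2 by 1.52 ± 0.19 on the log2 scale, while FOXF2 rose by 0.96 ± 0.13. Adjusted over the list alone, 14 were lower and 1 higher. The epithelial list fell as well, with 8 of 15 genes lower, 9 lower and 1 higher adjusted over the list alone, and a median of -0.65, or -0.21 to -0.24 under the limma settings (adjusted p = 0.00151; adjusted p = 0.924 with an estimated correlation). KRT19 fell from 22.5 ± 2.03 to 11.7 ± 2.83 FPKM, and ST14 (-1.42 ± 0.39), MARVELD2 (-1.21 ± 0.29) and ESRP2 (-1.06 ± 0.27) fell from an FPKM below 0.5 in Pri cells. The FPKM filter of the limma settings left out ST14, MARVELD2 and ESRP2, so the median there covers fewer members. ST14 lost its call without Pri library 1 (adjusted p = 0.115), Pri library 2 (0.0532), LM library 2 (0.0871) or LM library 3 (0.109). ESRP2 lost it without Pri library 2 (0.0639), Pri library 3 (0.0911) or LM library 3 (0.0737). The abundant keratins KRT8 (-0.68 ± 0.08) and KRT18 (-0.65 ± 0.07) were chosen after their values were seen.

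Growth factors and their receptors in MDA-MB-231 held 7 lower and 1 higher of 26 genes, and 10 lower and 1 higher adjusted over the list alone (adjusted p = 0.0412; adjusted p = 0.988 with an estimated correlation). IGFBP7 fell by 1.23 ± 0.09, PDGFRB by 0.66 ± 0.18 and the receptor kinase gene AXL by 0.60 ± 0.07, and the semaphorin and VEGF coreceptor gene NRP1 rose by 1.13 ± 0.11. Of 82 cytosolic ribosomal protein genes, 10 fell, 9 adjusted over the list alone, with a median of -0.08 (adjusted p = 0.0222; adjusted p = 0.988 with an estimated correlation). Among the falls there were RPL28 (-0.49 ± 0.07) and RPS16 (-0.46 ± 0.08). Without Pri library 1 the adjusted p of the growth factor list was 0.166 and that of the ribosomal list 0.258, and without LM library 3 both were 0.113; that of the growth factor list was 0.0870 without LM library 2. PDGFRB lost its call with limma (0.120) or without Pri library 1 (0.0982), Pri library 3 (0.0616), LM library 1 (0.0537) or LM library 2 (0.0768). Both lists also missed the threshold without the filter on low counts (adjusted p = 0.0855 each), and the growth factor list with an FPKM filter of 2 (0.0610) or the block (0.0766). The median of the ribosomal list was -0.038 without Pri library 1.

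The same question in 4T1 was met by libraries that spread more widely. Fkbp10 (chromosome 11, 100415697 to 100424824), which encodes a prolyl isomerase of the endoplasmic reticulum that acts on collagen, rose in LM cells from an FPKM of 0.440 ± 0.134 to 10.6 ± 4.15 (SD, n = 3), a log2 change of 4.63 ± 0.40 (SE, adjusted p = 0.0255). The tight junction gene Cldn3 (chromosome 5, 134986214 to 134987472) fell from 3.10 ± 0.82 to 0.106 ± 0.0708 FPKM, a log2 change of -4.86 ± 0.53 (adjusted p = 0.0394). Lsr (chromosome 7, 30957770 to 30973464) fell from 4.91 ± 3.36 to 0.128 ± 0.0142 FPKM, with a log2 change of -5.22 ± 0.56 (adjusted p = 0.0394). Adal (chromosome 2, 121140428 to 121156680), an adenosine deaminase-like gene, had 182 counts over the Pri libraries and 1 over the LM libraries, a ratio of 211 with a 95% interval of 37.4 to 8370 (adjusted p = 0.0285). These 4 were the genes called by edgeR among 14284 tested in 4T1, 1 higher and 3 lower, each with its LM libraries on one side of all Pri libraries. With library totals in place of TMM the split was 2 higher and 3 lower. Fkbp10 lost its call without Pri library 1 (0.0856), Pri library 3 (0.0952), LM library 2 (0.115) or LM library 3 (0.124), and Adal with replicate number as a block (0.0520) or without Pri library 1 (0.0856), Pri library 3 (0.0952) or LM library 1, 2 or 3 (0.0885, 0.224 and 0.172). Lsr lost it with limma on log2(FPKM + 0.5) (0.133) or without Pri library 1 (0.0512) or LM library 1, 2 or 3 (0.121, 0.294 and 0.263), and Cldn3 without any of the Pri libraries (0.129, 0.0575 and 0.0952 in turn) or LM libraries (0.121, 0.294 and 0.137). Lsr, Adal and Cldn3 fall below the FPKM of the naming rule for a single line and stand here as chosen after their values were seen.

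At an unadjusted p below the same threshold stood 1788 genes, 12.5% of those tested, and groups did not overlap for 18.7%, where chance gives 10%. The number called was 0 without Pri library 1, LM library 2 or LM library 3. It was 1 lower gene without Pri library 3, 1 higher gene without LM library 1, and 2 higher and 7 lower without Pri library 2. DESeq2 called 261 genes, edgeR without the filter on low counts 319, and limma on log2(FPKM + 0.5) 2 higher and 1 lower; the sets of the first 2 held the 4 genes above. Of the 4T1 lists below, limma called 1 gene in the epithelial list and 0 in each of the others.

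In 4T1 the epithelial list fell. All 12 tested genes had a negative log2 change, with a median of -0.67 (camera adjusted p = 4.12e-05; adjusted p = 0.444 with an estimated correlation). Of these, edgeR called 1 over all genes and 4 adjusted over the list alone: Cldn3, Krt7 (-3.44 ± 0.64), St14 (-1.09 ± 0.32) and Marveld2 (-0.99 ± 0.32). The most abundant members differed less, Krt18 by -0.23 ± 0.14, Krt8 by -0.12 ± 0.22 (0.046 without Pri library 1) and Tjp1 by -0.32 ± 0.13, none past the threshold. In the mesenchymal list 0 of 14 genes were called by edgeR over all genes, and 3 higher and 1 lower adjusted over the list alone (list adjusted p = 0.349). At an unadjusted p under 0.05 stood 7. DESeq2 called 1 higher and 1 lower, and edgeR without the filter on low counts 2 and 2, with an adjusted p of 0.0233 for Vim. Its most abundant members were Vim, with an FPKM of 534 ± 113 in Pri and 896 ± 132 in LM cells (SD, n = 3), Sparc (0.70 ± 0.27), Fn1 (-0.04 ± 0.24; 0.24 without Pri library 3 and 0.00088 without LM library 3) and Twist1 (0.59 ± 0.18). DESeq2 called 2 genes of the epithelial list, as did edgeR without the filter on low counts. Krt7 was called in both (adjusted p = 5.24e-06 and 0.000578) and without Pri library 2 (0.0447). Krt7, St14 and Marveld2 were chosen after their values were seen.

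The integrated stress and unfolded protein response list fell in 4T1 LM cells, with 23 of 27 genes lower and a median of -0.73 (adjusted p = 7.03e-06; adjusted p = 0.774 with an estimated correlation). Of these, 0 were called over all genes with edgeR and 5 with DESeq2, 16 had an unadjusted p under 0.05, and 7 were lower adjusted over the list alone. Without the filter on low counts edgeR called 10 (Atf4, adjusted p = 0.0118). Among the 7 was Atf4, the transcription factor of that response, at 178 ± 67.0 FPKM in Pri and 82.5 ± 17.5 in LM cells (SD, n = 3). Hspa5 (-0.23 ± 0.11), Cebpb (-0.27 ± 0.17) and Phgdh (-0.30 ± 0.15) were not past the threshold. From the mean of the libraries, the list's median was 0.071, 0.20 and 0.75 in Pri libraries 1 to 3. It was -0.57, -0.48 and -0.0060 in LM libraries 1 to 3, so LM library 3 lay close to Pri library 1. Inflammatory cytokines and NF-kB targets fell, 15 of 15 genes being lower with a median of -1.17 (adjusted p = 0.00295; adjusted p = 0.774 with an estimated correlation). By edgeR 0 were called over all genes or adjusted over the list alone, as by DESeq2, and 9 had an unadjusted p under 0.05. Without the filter on low counts edgeR called 5 (Cxcl5, adjusted p = 0.0233). Pri library 1 stood apart in this list, with a median 1.24 above the mean of the libraries against -0.14 and -0.16 in Pri libraries 2 and 3, and without it the list's median change was -0.36. The members named by abundance were Csf1 (-0.00 ± 0.27), Tslp (-0.06 ± 0.28), Nfkbia (-0.43 ± 0.45) and Cxcl5 (-4.08 ± 1.51). Nfkbia and Cxcl5 turned to 0.39 and 0.22 without Pri library 1, Csf1 to 0.022, 0.27 and 0.15 without Pri library 2, Pri library 3 or LM library 1, and Tslp to 0.12 and 0.21 without Pri library 1 or LM library 3.

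Subunits encoded by mitochondrial DNA fell in 4T1 LM cells as a list, with 11 of 11 genes lower, a median of -0.53 and 4 lower adjusted over the list alone (adjusted p = 0.000247; adjusted p = 0.774 with an estimated correlation). mt-Nd1 (-1.15 ± 0.38) and mt-Cytb (-0.62 ± 0.20) were among these 4, while mt-Co1 (-0.27 ± 0.14) and mt-Nd6 (-0.25 ± 0.24) were not. The median was -0.33 without Pri library 1 (adjusted p = 0.00787), and the median of Pri library 3 (-0.035 from the mean of the libraries) lay below that of LM library 1 (-0.024). By edgeR 0 passed over all genes, 5 had an unadjusted p under 0.05, DESeq2 called 1 and edgeR without the filter on low counts 2 (mt-Nd1, adjusted p = 0.0290). Nuclear genes of respiration had no calls, in a test that found 14.0% of simulated changes of fold 2. That share, 7 of 50 genes in 1 simulated set with far more calls than the real data, may overstate what the test could find. Of 37 complex I subunits 0 were called by edgeR over all genes or adjusted over the list alone (list adjusted p = 0.408). Among the most abundant were Ndufa8 (0.30 ± 0.19), Ndufb6 (0.19 ± 0.16) and Ndufc2 (0.02 ± 0.16). DESeq2 called 0 and 0 had an unadjusted p under 0.05. The 39 subunits of complexes II to V likewise had 0 calls by edgeR with either adjustment or by DESeq2, and 2 with an unadjusted p under 0.05 (list adjusted p = 0.349), with Atp5b at -0.05 ± 0.12, Cox8a at -0.02 ± 0.17, Atp5a1 at 0.36 ± 0.12 and Atp5c1 at 0.21 ± 0.16. Signs turned for Ndufc2 without Pri library 1, Pri library 3, LM library 2 or LM library 3 (-0.0050, -0.018, -0.024 and -0.033), for Cox8a without Pri library 2, Pri library 3 or LM library 1 (0.0018, 0.020 and 0.12), and for Atp5b without LM library 2 (0.0094). Genes of mitochondrial biogenesis and dynamics fell as a list, 15 of 19 being lower with a median of -0.32 (adjusted p = 0.00712; adjusted p = 0.774 with an estimated correlation). By edgeR 0 were called with either adjustment and 4 had an unadjusted p under 0.05, while DESeq2 called 2 and edgeR without the filter 1. Its most abundant members were Fis1 (0.35 ± 0.16), Mfn2 (0.11 ± 0.13), Pprc1 (-0.32 ± 0.21) and Esrra (-0.18 ± 0.16). Without Pri library 3 the median of that list was -0.16 (adjusted p = 0.138).

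Fatty acid oxidation genes in 4T1 had 0 of 29 called by edgeR over all genes or adjusted over the list alone, with a median of 0.12 (list adjusted p = 0.0752). Acaa2, the mitochondrial thiolase gene, had an FPKM of 19.2 ± 1.31 in Pri and 30.7 ± 4.03 in LM cells (SD, n = 3; adjusted p = 0.294, and 0.0189 with DESeq2). Acadl (0.16 ± 0.14), Acsl5 (0.07 ± 0.17) and Acsl4 (-0.57 ± 0.27) were also not past the threshold. The tricarboxylic acid cycle list (0 of 21 called by edgeR; list adjusted p = 0.840) held Sdhd (0.31 ± 0.21), Mdh2 (0.14 ± 0.12), Sdhb (0.29 ± 0.13) and Idh2 (0.16 ± 0.16). Its mean was -0.00 against a median of 0.01. The glycolysis list (0 of 22; list adjusted p = 0.829) held Pkm (0.12 ± 0.13), Eno1 (0.10 ± 0.11), Gapdh (-0.08 ± 0.13) and Aldoa (0.08 ± 0.16), with a median of 0.04 and a mean of -0.02. None of these was called adjusted over the list alone. At an unadjusted p under 0.05 stood 3 genes of fatty acid oxidation, 1 of the tricarboxylic acid cycle and 0 of glycolysis, and DESeq2 called 1, 0 and 0. Signs turned for Acsl5 (-0.069) and Aldoa (-0.046) without Pri library 3, for Aldoa without LM library 3 (-0.024) and for Gapdh without LM library 1 (0.024). Prkab1, of the AMPK list, turned to -0.039 and -0.14 without Pri library 1 or LM library 3. Of 9 AMPK subunits and upstream kinases, 0 were called by edgeR over all genes and 1 adjusted over the list alone, the upstream kinase gene Camkk2 (0.76 ± 0.19), chosen after its value was seen (list adjusted p = 0.408). It was also the 1 gene of the list at an unadjusted p under 0.05 and the 1 called by DESeq2 (adjusted p = 0.0412). Stk11 (0.22 ± 0.14), Prkag1 (0.23 ± 0.16) and Prkab1 (0.06 ± 0.22) were the most abundant beside Prkaa1.

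The S phase and DNA replication list rose in 4T1 LM cells, with 25 of 30 genes higher, a median of 0.34 and 0 called by either adjustment (adjusted p = 0.000255; adjusted p = 0.774 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit gene, had an FPKM of 57.1 ± 18.2 in Pri and 93.1 ± 10.3 in LM cells (SD, n = 3). Pcna (0.33 ± 0.15), Mcm6 (0.40 ± 0.17) and Mcm3 (0.30 ± 0.15) had the same sign. Genes of the G2/M phase, with 0 of 35 called by either adjustment (list adjusted p = 0.902), had a median of 0.03 and a mean of -0.07. They included Cdc20 (0.28 ± 0.16), Ccnb2 (0.36 ± 0.20) and Top2a (-0.19 ± 0.12) beside Plk1. Cholesterol synthesis and uptake rose as a list, 19 of 21 genes being higher with a median of 0.41 and 0 called by either adjustment (adjusted p = 0.000634; adjusted p = 0.818 with an estimated correlation). Srebf2 (0.05 ± 0.21) and Insig1 (0.72 ± 0.30) were among the most abundant. Growth factors and their receptors rose, 21 of 27 being higher with a median of 0.32, 0 called over all genes and 3 adjusted over the list alone (adjusted p = 0.00529; adjusted p = 0.774 with an estimated correlation). The most abundant were Igfbp4 at 0.68 ± 0.24, Axl at -0.20 ± 0.15, Nrp2 at -0.02 ± 0.12 and Igf2r at 0.33 ± 0.21. Of the lists with 0 called here, 10 genes of the S phase, 4 of the G2/M phase, 2 of the cholesterol and 10 of the growth factor list had an unadjusted p under 0.05 with edgeR. In these lists DESeq2 called 0, 2, 0 and 3 genes in turn, and edgeR without the filter on low counts 0, 2, 0 and 4. Srebf2 turned to -0.14 without Pri library 3, and Nrp2 to 0.046 and 0.020 without Pri library 3 or LM library 3. Without Pri library 3 the median of the cholesterol list was 0.11 (adjusted p = 0.197), that of the growth factor list 0.051 (0.0809) and that of the S phase list 0.19 (0.00740). The cholesterol median was 0.25 without LM library 1 and the growth factor median 0.19 without LM library 3. In the cholesterol list Pri library 3 stood lowest, with a median 0.93 below the mean of the libraries, while Pri library 1 (0.27 above) lay over LM libraries 2 and 3. In the growth factor list the median of LM library 1 (-0.079) lay below those of Pri library 1 (-0.076) and Pri library 2 (-0.038).

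**Figure D2:**
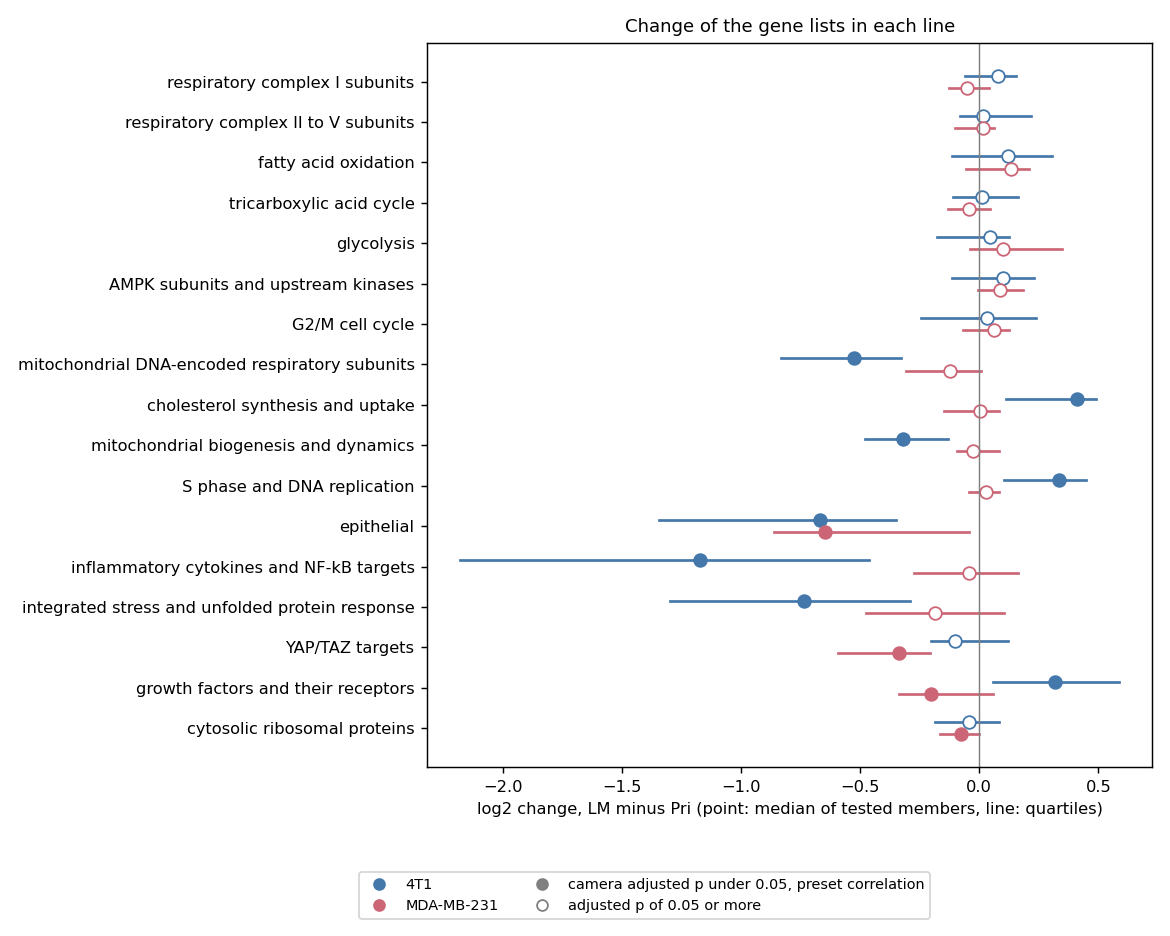
Log2 change, LM minus Pri (horizontal axis), of gene lists in 4T1 (blue) and MDA-MB-231 (red); points are the median of the tested members, lines run between the quartiles, and filled points have a camera adjusted p under 0.05 with the preset correlation, 8 in 4T1 and 4 in MDA-MB-231 (2 without its Pri library 1 or LM library 3). The epithelial list has a median of -0.67 in 4T1 (-0.42 with limma on log2(FPKM + 1)) and -0.65 in MDA-MB-231. The latter was -0.21 to -0.24 with limma, which left out members of low FPKM. With an estimated correlation no list passes in either line, and other groupings of the same libraries passed up to 12 and 8 lists.

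Genes that move alike in both lines address whether the LM derivatives share changes across species. LSR, which encodes a receptor at tricellular junctions, was the 1 gene called in the same direction in both lines, at -5.22 ± 0.56 in 4T1 and -4.16 ± 0.25 in MDA-MB-231 (SE). Independent lists of lower genes would share 0.25 genes of the 9527 tested in both (Fisher's exact p = 0.230), and 0 genes were called in opposite directions by edgeR or limma, 19 by DESeq2 and 18 by edgeR without the filter on low counts. Without 4T1 Pri library 2 there was 1, ITGA2. MYO1D, called in MDA-MB-231 (-3.06 ± 0.17), had a log2 difference of -3.17 ± 0.39 for Myo1d in 4T1 (adjusted p = 0.0686), named there after its value was seen. Myo1d was called in 4T1 with DESeq2 (8.50e-11), without the filter on low counts (0.000121) and without Pri library 2 (0.0447). Of the 1745 genes called in MDA-MB-231 and tested in both lines, 943 (54.0%) had the same sign in 4T1. Among those with an absolute log2 change of at least 1 these were 41 of 84 higher (48.8%) and 40 of 86 lower genes (46.5%). Of all genes tested in both lines, 48.9% were higher in 4T1 LM cells. Of all called genes higher in MDA-MB-231, 55.1% were higher in 4T1, and of the lower ones 52.8% were lower. Across these 9527 genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.0849 and Spearman's rho of 0.0753. The number called alike was 0 without 4T1 Pri library 1 or any 1 of the 4T1 LM libraries, 2 without 4T1 Pri library 2, 48 without the filter on low counts and 38 with DESeq2. The adjusted p of Lsr in 4T1 was 0.0512 without Pri library 1 and 0.121, 0.294 and 0.263 without LM libraries 1 to 3.

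The difference between the lines in the LM against Pri change was tested for 11284 genes. The fit shares 1 estimate of spread over both lines, so it understates the error of the more variable 4T1 libraries. ADAL had the lowest p, its log2 change being 7.06 ± 0.60 (SE) lower in 4T1 than in MDA-MB-231, where its FPKM was 2.15 ± 0.11 in Pri and 2.02 ± 0.25 in LM cells (SD, n = 3). That SE is too narrow for a gene with 1 count over the 4T1 LM libraries, whose count ratio had a 95% interval of 37.4 to 8370. FKBP10 had a change 4.42 ± 0.40 higher in 4T1, with an FPKM of 21.9 ± 1.76 and 25.5 ± 2.73 in MDA-MB-231 Pri and LM cells. MATN2, a matrix protein gene, fell in MDA-MB-231 (-3.04 ± 0.15) and had -0.08 ± 0.26 in 4T1, and the phosphodiesterase gene PDE4B rose by 1.75 ± 0.22 in MDA-MB-231 and had -1.39 ± 0.25 in 4T1. In all, edgeR called 162 genes, 87 with a higher and 75 with a lower change in 4T1. That count was 692, 347 and 502 without 4T1 Pri library 2, Pri library 3 or LM library 1, 31 and 67 without 4T1 LM library 2 or 3, and 28, 33, 36, 29, 43 and 34 without MDA-MB-231 Pri libraries 1 to 3 and LM libraries 1 to 3 in turn.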

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

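The tests of shared paralog reads, of single Pri libraries, of transcripts found in leukocytes alone and of the splits that keep MDA-MB-231 whole were chosen only after the result was seen. The bounds of the other tests were written before those tests were run. The patterns on chromosome 5, in the inflammatory and stress lists and in the YAP/TAZ list were themselves taken from these data.

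The interaction term singled out 6 genes whose LM against Pri change differed between the lines, given as the log2 change in 4T1 minus that in MDA-MB-231. ADAL differed by -7.06 ± 0.60 (SE) and FKBP10 by 4.42 ± 0.40. MATN2 differed by 2.96 ± 0.31 and PDE4B by -3.14 ± 0.37. GRAMD1B differed by 5.97 ± 0.72, with 1 count over the MDA-MB-231 LM libraries against 108 over the Pri libraries, a ratio of 123 with a 95% interval of 21.6 to 4896. With limma on log2(FPKM + 0.5) its difference was -0.086 (adjusted p = 0.853), and it was called under none of the 5 limma settings. STXBP6 differed by 7.55 ± 0.91, with 3 counts in MDA-MB-231 LM against 432 in Pri libraries, a ratio of 164 with a 95% interval of 55.7 to 797. The 162 genes called for this difference were equalled or exceeded in 4 of 100 drawn splits of both lines, the real one included, the highest other count being 277. Splits that broke up the Pri and LM groups of MDA-MB-231 gave at most 4 genes, since they remove the strong contrast of that line. The split with 277 kept the groups of both lines whole and swapped the direction of 1 line, so it is no other grouping. Of the 13 splits that kept MDA-MB-231 whole and broke up 4T1, 2 gave as many (201 and 185), both with Pri libraries 1 and 3 beside LM library 1. These are too few for a share under 0.05. For the 1 gene called alike in both lines, 1 of 100 drawn splits, the real one, gave as many, and the highest other count was 0. Every other split of either line called 0 genes, which fixes that count at 0, so the splits do not decide whether chance can be excluded.

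In the splits of single lines, 3 against 3 libraries make 10 splits, too few for a share under 0.05, though they can show that other groupings reach as much. In MDA-MB-231 the 2609 called genes were reached in 1 of 10 splits, the real one, and the highest other count was 0. In 4T1 the 4 called genes were reached in 1 of 10 splits and the highest other count was 0, although the split that grouped Pri libraries 1 and 3 with LM library 1 gave 2001 genes at an unadjusted p under 0.05 against 1788 in the real split. As many lists as the 8 of 4T1 passed camera in 7 of 10 splits, with up to 12 in another split. As many as the 4 of MDA-MB-231 passed in 3 of 10, with up to 8. Other groupings of the same libraries thus passed as many lists, so these numbers do not set the Pri and LM groups apart in either line.

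On mouse chromosome 5, neighbouring genes were higher in 4T1 LM cells: Sri (1.17 ± 0.20, SE), the drug efflux pump gene Abcb1b (1.49 ± 0.20), Crot (1.57 ± 0.23), which encodes a peroxisomal carnitine acyltransferase, and Tmem243 (1.71 ± 0.28), named after their values were seen, none past the threshold over all genes with edgeR after the filter on low counts (lowest adjusted p = 0.0871), but all past it without that filter (highest adjusted p = 0.00248) and with DESeq2. Among the 200 genes of lowest p over the whole genome, 32 close pairs had the same direction. Of 1000 shuffles of positions, 0 gave as many (highest shuffle 24), so these genes as a whole lie closer than chance placement gives. The pairs include genes of this segment and overlapping genes such as Lcmt2 and Adal. The count therefore does not test the segment apart from the genes that prompted it. Reads shared with the paralog Abcb1a do not account for Crot, Tmem243 and Sri, whose median was 1.57. Those genes were chosen for being higher, so their median is no separate test. A gain of the segment may underlie the pattern: without the paralog Abcb1a (1.55 ± 1.13), which was left out, the 9 other tested genes between 7046078 and 10160986 had a median of 1.15 (quartiles 0.71 and 1.41), 8 of them higher. Not all are independent: 7330423F06Rik lies inside Abcb1b, Gm5106 overlaps its start, and Tubb4b-ps1 and Gm7332 are processed pseudogenes. Of the coding genes, Dbf4 (0.71 ± 0.15), Slc25a40 (1.01 ± 0.21), Rundc3b (1.15 ± 0.34) and the scarce 9330182L06Rik (2.86 ± 0.65) were higher. Dmtf1, inside the segment at -0.35 ± 0.32, did not follow. DNA copy number was not analysed here, so regional regulation stays open as well.

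In 4T1, the inflammatory and stress response lists were lower in LM cells, by a median of -1.17 and -0.73. The inflammatory difference rests largely on Pri library 1, since the median was -0.36 without it (adjusted p = 0.0117), while the stress difference does not rest on Pri library 3 alone, the median being -0.56 without it (adjusted p = 5.98e-06). Leukocytes among the Pri cells were tested by 12 leukocyte markers, which summed to 6.39% of the FPKM of the inflammatory list, between the bounds of 1% and 10% set beforehand. Cd14 (11.8 ± 6.92 FPKM, SD, n = 3), Cd74 and Cd68 made up most of it. Cd74 went from 9.67 ± 6.21 FPKM in Pri to 1.86 ± 1.43 in LM cells and Cd68 from 4.20 ± 0.78 to 1.93 ± 0.43, while Cd14 stood at 11.7 ± 1.81 in LM cells. Ptprc, Laptm5, Lyz2 and Cd52, abundant in leukocytes, summed to 0.00382% with 4 counts over the Pri libraries. They were picked from the 12 after the marker values were seen, so their low sum is no separate test. Among the markers left out of it, Coro1a had 94 and Csf1r 37 counts over the Pri libraries. Leukocytes as a source thus stay undecided by the bounds set beforehand. A difference in culture state between the Pri libraries and a difference between the cells themselves stay open.

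In MDA-MB-231, YAP/TAZ targets were lower in LM cells by a median of -0.34. The gene length and abundance of the list are argued against, since 0 of 10000 random lists matched for both reached so low a median (lowest -0.19). A wider fall of actin-responsive SRF targets stays open: 20 such genes had a median of -0.082, with quartiles of -0.24 and 0.05, and TAGLN, TPM1, FHL2 and ACTN1 fell while TPM4 rose. Lower YAP or TAZ activity in the LM cells is a candidate explanation that these counts do not test, and the list's adjusted p was 0.967 with an estimated correlation. In 4T1, where edgeR called 4 genes in all, the list had a median of -0.10 with 0 of 21 genes called (camera adjusted p = 0.783). Cell density at harvest, which the labels do not give, stays open.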

How the results depend on the processing

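The alternative of library totals without TMM was chosen only after the data had been seen; all other settings were fixed beforehand. The 4 genes called in 4T1 became 319 without the filter on low counts, 261 with DESeq2, 2 with limma on log2(FPKM + 1), 2 with limma on quantile-normalized log2(FPKM + 0.5) and 0 to 9 with 1 library left out. The median prior degrees of freedom of the edgeR fit were 4.45 with the filter and 19.8 without it, which bears on the first of these; the cause was not tested for the others. The 2609 genes of MDA-MB-231 became 1701, 1682 and 1700 with limma on FPKM with pseudocounts of 0.5, 0.1 and 1, 1678 with TPM, 1720 with quantile normalization, 506 with an absolute log2 change of at least 1, and 1499 to 2698 with 1 library left out. With replicate number as a block they became 4398, although not every library correlated best with its own number (same-number correlations of deviations 0.353, 0.0961 and 0.105, others up to 0.199). The limma settings, TPM and quantile normalization among them, tested 15314 genes against 16792 in MDA-MB-231 and 12520 against 14284 in 4T1. Filter and tool thus changed together there. Lists past the threshold went from 8 in 4T1 and 4 in MDA-MB-231 to 0 in each with an estimated correlation, from 4 to 2 in MDA-MB-231 without the filter, and to 2 to 5 there with 1 library left out. A planted list of 30 genes shifted by 0.5 was missed in 4T1 with an estimated correlation (adjusted p = 0.351) and found in MDA-MB-231 (0.0265). The simulated genes were drawn independently of one another. The real YAP/TAZ list of MDA-MB-231 had an estimated correlation of 0.117, so the simulation may overstate what this setting could find. Genes called alike in both lines, 1 in the main setting, became 48 without the filter, 2 with the block, 38 with DESeq2, 0 with limma on log2(FPKM + 0.5), 0 with log2(FPKM + 1), 0 with quantile normalization, and 0 to 2 with 1 library left out. The 162 genes that differed between the lines became 794 with DESeq2, 310, 262 and 334 with limma at pseudocounts of 0.5, 0.1 and 1, 269 with TPM, 341 with quantile normalization and 28 to 692 with 1 library left out; the cause was not tested. Signs reversed for GRAMD1B between the lines with limma at 0.5 (-0.086), at 1 (-0.16) and with quantile normalization (-0.036), where its low FPKM lies under the pseudocount; its call was also lost at 0.1 (adjusted p = 0.254) and with TPM (0.264). At a pseudocount of 1 the calls of ADAL (0.0545) and STXBP6 (0.0700) between the lines were lost. The sign of Ndufc2 in 4T1 reversed with library totals without the 20 most abundant genes (-0.0063), with limma at 0.5, 0.1 and 1 (-0.0041, -0.0042 and -0.0040), with TPM (-0.012) and with quantile normalization (-0.054). That of Csf1 reversed with the block (0.047), with limma at 0.5, 0.1 and 1 (0.026, 0.026 and 0.025) and with TPM (0.018), and that of Fn1 with the block (0.019). MT-ATP6 in MDA-MB-231 reversed with the block (0.044), with limma at 0.5, 0.1 and 1 (0.060, 0.060 and 0.060), with TPM (0.054) and with quantile normalization (0.043). With 1 library left out, signs reversed in MDA-MB-231 for PLK1 (-0.072 to 0.049), PRKAA1 (-0.12 to 0.064), PRKAA2 (-0.010 to 0.23), NDUFS4 (-0.098 to 0.0019), MT-CO3 (-0.15 to 0.33), MT-ATP6 (-0.33 to 0.33) and MT-ND1 (-0.43 to 0.16). In 4T1 they reversed for Prkaa1 (-0.23 to 0.0036), Ndufc2 (-0.033 to 0.12), Atp5b (-0.096 to 0.0094), Cox8a (-0.16 to 0.12), Acsl5 (-0.069 to 0.20), Gapdh (-0.16 to 0.024), Aldoa (-0.046 to 0.16), Prkab1 (-0.14 to 0.23), Srebf2 (-0.14 to 0.31), Krt8 (-0.32 to 0.046), Csf1 (-0.24 to 0.27), Tslp (-0.31 to 0.21), Nfkbia (-0.78 to 0.39), Cxcl5 (-4.71 to 0.22), Nrp2 (-0.063 to 0.046) and Fn1 (-0.28 to 0.24). RGCC kept its direction and call in MDA-MB-231 under every setting (1.72 to 2.19), and Rgcc kept its direction in 4T1 (1.85 to 2.42) and was called in none of the settings that gave it an adjusted p; it did not enter the limma settings or the FPKM filter, and DESeq2 gave none. Of the remaining values for single genes, lists and direction counts, 3406 stayed the same, 128 lost the call and 35 gained it. Staying the same means direction and side of the threshold for genes and lists, and a similar size for direction counts. A further 38 direction counts moved beyond that size. IDH3A, CENPF, PDGFRB, PRKAG2, CAB39, MMP11 and L1CAM in MDA-MB-231 were called under none of the 5 limma settings (L1CAM, adjusted p 0.0576 to 0.0597). Without the filter SUCLG2 (0.0575) and ATP5MF (0.0546) lost their calls. TNC missed the threshold with limma at 0.1 (0.0505) and 1 (0.0507) and with quantile normalization (0.0531). The median of the MDA-MB-231 epithelial list was -0.21 to -0.24 with limma, and that of 4T1 -0.42 with limma at 1. In MDA-MB-231 the FPKM filter of the limma settings left out ST14, MARVELD2 and ESRP2, so the list's members changed too. Rgcc had 4 to 5 counts per 4T1 Pri library, and whether depth or the spread of 4T1 limits its test was not examined.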

Other observations

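No further tests were chosen after the result was seen for the gene groups given here; the groups were fixed before the data were examined.

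Matrix, adhesion and hypoxia genes moved both ways in MDA-MB-231 LM cells. Of 21 integrin and adhesion genes 7 rose and 4 fell, 7 and 6 adjusted over the list alone (list adjusted p = 0.753). ITGA2, the collagen-binding integrin subunit gene, rose from 31.5 ± 2.54 to 77.1 ± 13.1 FPKM (SD, n = 3), ITGA1 by 0.79 ± 0.08 and ITGB4 by 0.66 ± 0.13 on the log2 scale, and L1CAM fell by 1.11 ± 0.20 (not called with limma, adjusted p = 0.0576). Of 24 matrix genes 7 rose and 7 fell, 9 and 7 adjusted over the list alone (list adjusted p = 0.949), with SPARC (1.07 ± 0.09), COL6A2 (1.00 ± 0.09) and TNC (0.84 ± 0.17; 0.55 without LM library 1, adjusted p = 0.0507 with limma on log2(FPKM + 1)) higher and FN1 (-1.63 ± 0.09) lower. Among 25 matrix proteases and inhibitors 6 rose and 5 fell, 7 and 7 adjusted over the list alone (list adjusted p = 0.965). The membrane protease gene MMP14 rose from 20.5 ± 0.83 to 44.5 ± 10.4 FPKM and MMP11 by 0.94 ± 0.25, while the protease inhibitor gene TIMP3 (-1.31 ± 0.09) fell. MMP11 lost its call with limma (0.109) or without Pri library 2 (0.0936), Pri library 3 (0.0679) or LM library 1 (0.0684). In the mesenchymal list 6 of 17 genes rose and 4 fell, 6 and 5 adjusted over the list alone, with SNAI2 (-1.62 ± 0.17) and TAGLN (-2.09 ± 0.34) lower beside FN1. The list's median was 0.22, its mean -0.08 and its camera direction up (adjusted p = 0.753). Of 24 hypoxia response genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone (list adjusted p = 0.284), with NDRG1 (1.38 ± 0.15), BNIP3 (0.67 ± 0.08) and EGLN3 (0.61 ± 0.12) higher and ADM (-2.54 ± 0.28) lower.

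Of 12 tested genes of a published lung metastasis signature, 5 rose and 3 fell in MDA-MB-231 LM cells, 5 and 4 adjusted over the list alone (list adjusted p = 0.445). LTBP1 (1.51 ± 0.21), KYNU (1.22 ± 0.09) and SPARC were higher and NEDD9 (-2.32 ± 0.20) lower. The latent TGF-beta binding protein gene LTBP2 rose by 1.61 ± 0.15, one of 5 higher and 4 lower of 20 TGF-beta targets and ligands, 5 and 7 adjusted over the list alone (list adjusted p = 0.988). In the stress response list 1 of 27 genes rose and 7 fell, 4 and 9 adjusted over the list alone (list adjusted p = 0.0595). The amino acid transporter gene SLC7A5 fell from 104 ± 4.78 to 61.0 ± 5.30 FPKM (SD, n = 3), ATF3 by 1.00 ± 0.15 and CHAC1 by 0.82 ± 0.17, and VLDLR rose by 0.74 ± 0.11. Of 30 type I interferon response genes 6 rose and 2 fell, 8 and 2 adjusted over the list alone (list adjusted p = 0.0595), with GBP2 (1.20 ± 0.14) and IFI44 (0.72 ± 0.15) higher and OAS3 (-1.19 ± 0.13) and OAS1 (-2.04 ± 0.37) lower. Among 11 inflammatory genes, CSF1 fell by 0.39 ± 0.08 beside CCL2 and IL11, 3 by either adjustment (list adjusted p = 0.658). In 4T1, 0 genes of these lists were called over all genes by edgeR or by limma, and DESeq2 called from 0 to 5 per list. Without the filter on low counts edgeR called from 0, in the interferon list, to 10, in the stress response list. At an unadjusted p under 0.05 with edgeR stood between 1 gene, in the interferon list, and 16, in the stress response list.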
